A study of Homo sapiens with 6 samples.

How the data were processed

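RNA-seq was analysed for 6 libraries of cells described as PLC/PRF/5, 3 sensitive and 3 resistant to lenvatinib. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were grown with 10% serum, medium of the resistant cells was changed every 48 h and cells were passaged at 90% confluence, and libraries were made from 1.5 µg of total RNA. The same labels mention a Bioanalyzer in the library step and no selection of poly(A) RNA or removal of ribosomal RNA.

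The authors deposited 1 table per library with 1 value per gene symbol, and the unit was inferred from the values as FPKM, normalized by the authors to transcript length and library size. RPKM would look the same. Reads were trimmed with cutadapt and aligned with HISAT2, per the submitters' processing notes, and the versions, the counting program, the genome build, the annotation and the strand setting are not given in the sources used here. Column sums differed between libraries, unlike TPM or CPM. Of 8708 genes with a mean above 0 and below 1 FPKM, 99.9% had values in whole multiples of a gene-specific step, within 0.02 of a step. The step was inversely related to transcript length, and 966 genes with a single transcript in GENCODE release 29 implied 39700000 reads or fragments (quartiles 39500000 and 47000000). The steps of the 6 libraries lay within 3.5% of each other, so depth did not separate the groups. Read counts are not analysed here. A value of 0 can be a failed estimate, so a group at 0 is given as listed at 0 with no fold change.

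Of 24432 symbols, 23056 matched the RefSeq gene table by symbol and 270 by synonym, and 1106 did not match. No 2 replicates were duplicates, since no nonzero value was identical between any pair and the whole steps of replicate pairs differed by a chi-square of 6.26 to 38.24 per degree of freedom.

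Genes were tested in R 4.3.3 with limma 3.58.1 (limma-trend) on log2(FPKM + 1), with a pseudocount of 1, for genes of at least 1 FPKM in at least 3 samples, all 6 samples in 1 fit of group with no block. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over all tested genes). The fit had 4 residual and 2.75 prior degrees of freedom. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Deviations are given as SD over 3 libraries of FPKM, and standard errors are those of limma on the log2 scale.

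Before the data were examined, 39 gene lists were fixed, 30 of biology, 5 of other cell types and 4 of library quality, with 707 of 727 members in the files. They cover the title's genes, COP9 signalosome, EGFR family, MAPK/ERK output, lenvatinib's target receptors, other receptor kinases and growth factors, ABC transporters, hepatocyte, drug metabolism, fetal and progenitor, mesenchymal, epithelial, G2/M, S phase, cholesterol, fatty acid, unfolded protein response, NRF2, hypoxia, glycolysis, interferon, antigen presentation, inflammation, p53, Wnt, YAP/TAZ, TGF-beta and BMP, metallothionein, lysosome and Golgi genes. The others cover fibroblast, endothelial, leukocyte, cholangiocyte and erythroid markers and mitochondrial, ribosomal protein, histone and housekeeping genes. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. The counts of members past the threshold were taken with the adjustment over all genes and adjusted over the list alone. Some genes are on more than 1 list.

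Named genes were fixed by a rule. They are GOLM1, COPS5 and EGFR, the 10 largest changes in each direction among called genes whose groups did not overlap and whose mean was at least 5 FPKM, without clone, noncoding-locus or antisense names, and up to 4 called members of each list by size of change (or the 2 with the highest mean where fewer than 2 passed). Some genes that the rule names are not reported here.

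The fit was tested on simulated data with 200 genes changed among 10880. It recovered 23.9% of 1.5-fold, 56.7% of 2-fold and 90.9% of 4-fold changes and called 7 unchanged genes. Far fewer genes changed there than the 67.7% called in the real comparison, and the Benjamini-Hochberg cutoff depends on that share. These recovery rates thus do not carry over to the real comparison. Of 400 random lists, 2.8% had a camera p under 0.05. Simulated genes were drawn independently, so this rate does not cover lists whose genes vary together.

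Alternatives fixed before the data were examined were quantile normalization, scaling to the geometric mean sample, limma without the trend, robust limma-trend, no filter, a mean of at least 5 FPKM, a pseudocount of 0.1, the replicate number as a block, a test against a 1.5-fold change, each library left out, and for lists an estimated correlation, fry and camera on ranks. With an estimated correlation, camera tests on the 4 residual degrees of freedom of the fit, which leaves it little power here. When a library was left out, the genes tested stayed those of the full fit. Rescaling each library without its mitochondrial mRNAs was chosen after seeing the data, as were 8 families of gene symbols in the closing section.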

Results

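The series profiled RNA from cells described as PLC/PRF/5, an established human hepatocellular carcinoma line, in 2 states with 3 libraries each. Whether the resistant libraries came from that line stays open, as the closing section sets out. Rises and falls below compare the libraries as labelled. Sensitive cells were the untreated control. Resistant cells had been grown in rising doses of lenvatinib, an oral kinase inhibitor that blocks VEGF and FGF receptors and is used against liver cancer. The labels give a starting dose of 20 µmol/L, steps of 0.5 mmol/L at each passage and a final dose of 40 mmol/L, so the units of the start and of the steps do not match. Only the resistant libraries carry the lenvatinib label, so drug exposure and resistance could not be separated in any comparison. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The series title names GOLM1, the CSN5 protein encoded by COPS5, and EGFR signaling, and these genes set the question for the comparison.

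The values covered 24432 gene symbols per library, of which 1911 were at 0 in all 6 libraries. Between 10391 and 10916 genes reached 1 FPKM in a library. No read counts were analysed here, but the spacing of the low values put the depths of the 6 libraries within 3.5% of each other, at an implied 39700000 reads or fragments each. Summed FPKM ranged from 410491.6 to 475088.1 in the sensitive and from 366048.4 to 377923.0 in the resistant libraries. Resistant replicates correlated at Pearson's r of 0.9939 to 0.996 across tested genes, on log2(FPKM + 1), where genes are not independent replicates. Sensitive replicates 1 and 2 reached 0.9947, whereas sensitive replicate 3 stood at 0.9515 and 0.9643 from them. Libraries of different groups correlated at 0.68 to 0.706.

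All 23 tested hepatocyte transcripts fell, and all 5 tested metallothioneins and 15 of 20 tested inflammatory genes rose. The transcript with the largest rise was S100A6, a calcium-binding protein, from 1.91 ± 0.545 FPKM in sensitive to 2020 ± 176 FPKM in resistant cells (mean ± SD, n = 3 in each group here and below), a log2 fold change of 9.45. S100A11 rose by 9.31, the urokinase gene PLAU by 9.08, the metallothioneins MT1E and MT2A by 8.96 and 8.26, the lactate dehydrogenase subunit LDHB by 8.24, IGFBP4 by 8.12, the cytokine IL6 by 8.02, the tetraspanin CD9 by 7.73 and PADI2 by 7.37 on the log2 scale. Among the falls, AMBP went from 991 ± 282 to 4.53 ± 2.47 FPKM, a log2 fold change of -7.54. The fibrinogen chains FGA and FGG, at -7.50 and -7.16, fell with angiotensinogen (AGT, -7.45), alpha-1-antitrypsin (SERPINA1, -7.41), A2M (-7.18) and vitronectin (VTN, -7.18). UCA1, a long noncoding RNA, the cancer-testis antigen gene MAGEA4 and TM4SF5 completed the 10 largest falls, at -7.34, -7.09 and -7.07. Fold changes are on the log2(FPKM + 1) scale throughout and understate the change of genes at low values. A gene under 1 FPKM in every library of 1 group passed the filter only through the other group, which fixed its direction.

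Of 11694 genes tested, 7920 (67.7%) differed between resistant and sensitive cells at an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment. Of these, 4117 were higher and 3803 lower in resistant cells, and 4465 differed at least 2-fold (2298 higher and 2167 lower). Resistant and sensitive values did not overlap for 74.4% of tested genes, against 10% by chance. A stricter filter or a test against a 1.5-fold change lowered the count of 7920 by more than 1.5 times, to 4973 and 4357 genes. The stricter filter tested only 7396 genes, of which 67.2% were called, against 67.7% in the main fit. Without sensitive replicate 3 the count was 9442, and without resistant replicate 2 it was 6675.

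**Figure D1:**
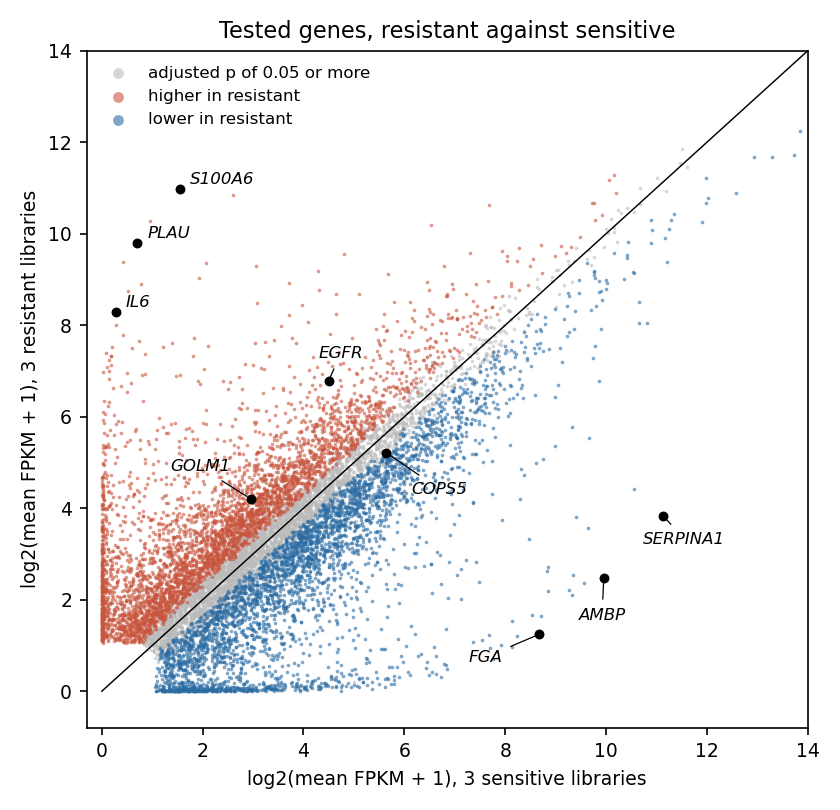
Mean level of each tested gene in the 3 resistant libraries (vertical axis) against the 3 sensitive libraries (horizontal axis), both as log2(mean FPKM + 1), with genes that passed the test coloured by direction and the diagonal marking equal levels. S100A6, PLAU and IL6 lie near the left edge at high resistant levels, SERPINA1, AMBP and FGA lie far below the diagonal, and COPS5 lies just below it.

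Both EGFR and GOLM1 were higher in resistant cells, and COPS5 did not pass the test. GOLM1, a Golgi membrane glycoprotein, rose from 6.72 ± 2.25 to 17.5 ± 1.03 FPKM (log2 fold change 1.30, SE 0.224, adjusted p = 0.00188 in limma with Benjamini-Hochberg adjustment, every resistant library above every sensitive one). EGFR rose from 21.6 ± 11.5 to 109 ± 11.7 FPKM (log2 fold change 2.46, SE 0.437, adjusted p = 0.00215). Its level was 27.9, 28.6 and 8.33 FPKM in sensitive replicates 1, 2 and 3, and without sensitive replicate 3 the log2 fold change of EGFR was 1.91. COPS5, the catalytic subunit of the COP9 signalosome, was at 48.9 ± 9.66 FPKM in sensitive and 36.2 ± 2.00 in resistant cells (log2 fold change -0.40, adjusted p = 0.0605). Without sensitive replicate 3, in which COPS5 was at 37.7 FPKM against 54.8 and 54.1 in the other sensitive libraries, COPS5 passed as lower in resistant cells (log2 fold change -0.58, adjusted p = 0.000113), as it did under scaling to the geometric mean sample (-0.42, adjusted p = 0.0358). Adjusted over the list alone, these 3 genes gave 2 higher and 1 lower. The title chose them, possibly from these same samples, so their count is not independent evidence of direction, and camera found no shift of the list (adjusted p = 0.596).

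The COP9 signalosome, which removes NEDD8 from cullins, did not move as a unit. Of its 10 subunits 3 rose, 1 fell and 6 did not pass, and 2 rose and 1 fell adjusted over the list alone. COPS3 rose from 44.6 ± 1.94 to 187 ± 6.85 FPKM (log2 2.05), and COPS7A and COPS8 rose by 0.61 and 0.57, whereas GPS1 fell by 1.21. The list's median was -0.10 and its mean 0.06, with the camera test on the lower side (adjusted p = 0.987), which turned to the higher side under quantile normalization and without sensitive replicate 2, resistant replicate 2 or resistant replicate 3. Leaving out any library except sensitive replicate 3 ended the call of COPS7A (adjusted p from 0.0877 to 0.108). Scaling to the geometric mean sample (limma adjusted p = 0.0597) and testing with no filter (0.0643) ended it as well. Without sensitive replicate 3, 4 subunits were lower, and under quantile normalization and scaling to the geometric mean sample 2 and 3 were.

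**Figure D2:**
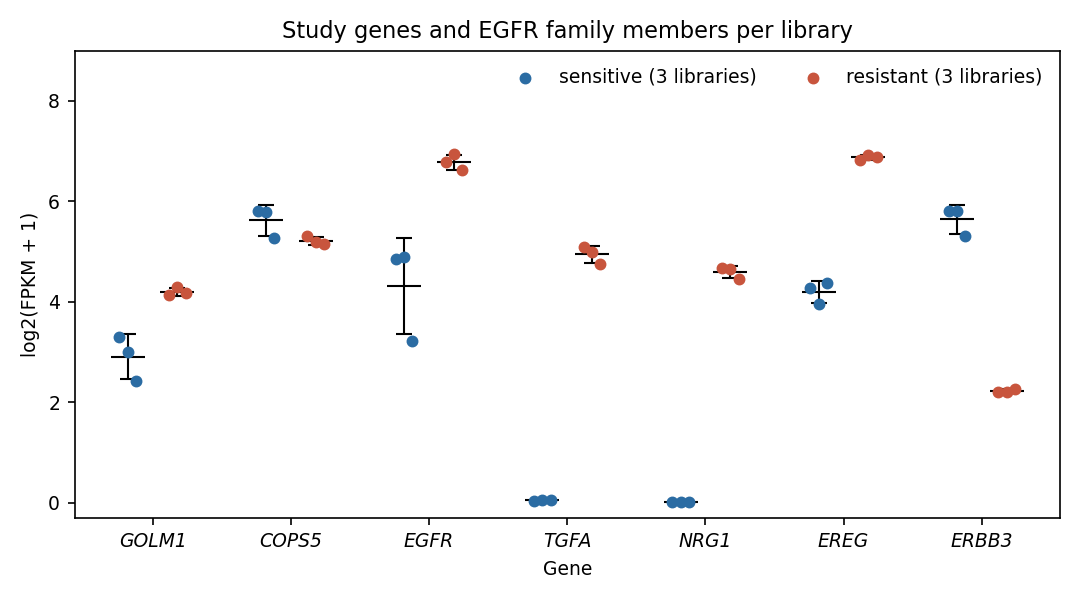
Level of GOLM1, COPS5, EGFR and 4 further members of the EGFR family list in each of the 6 libraries, as log2(FPKM + 1), with points for single libraries and bars for the mean ± SD of the 3 libraries of a group. TGFA and NRG1 lie near 0 in all sensitive libraries, and the sensitive library with the lowest EGFR, at 8.33 FPKM, is replicate 3.

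Some ligand genes of the EGFR family rose with the receptor. TGFA went from 0.0366 ± 0.00844 to 30.0 ± 3.59 FPKM (log2 4.89), the ERBB3 and ERBB4 ligand NRG1 from 0.00729 ± 0.00186 to 23.2 ± 1.94 FPKM (4.58), and epiregulin (EREG) from 17.5 ± 2.70 to 117 ± 4.30 FPKM (2.68). ERBB3, a kinase-impaired partner receptor, fell from 49.6 ± 9.63 to 3.68 ± 0.104 FPKM (-3.42). Of 9 tested members of the EGFR family list 6 rose, 1 fell and 2, ERBB2 and the ligand gene AREG, did not pass (camera adjusted p = 0.0244). The list's call was lost with an estimated correlation (adjusted p = 0.22 with an estimated correlation).

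Of 20 tested transcripts that report ERK pathway activity 16 rose, 2 fell and 2 did not pass (camera adjusted p = 0.00226, and adjusted p = 0.203 with an estimated correlation). The AP-1 subunit FOSL1 rose from 3.31 ± 2.38 to 187 ± 15 FPKM (log2 5.58), the ERK phosphatase DUSP5 from 7.48 ± 1.84 to 357 ± 37.9 FPKM (5.42), the receptor EPHA2 from 14.6 ± 3.75 to 345 ± 21.3 FPKM (4.49) and ERRFI1, a feedback inhibitor of EGFR, from 21.9 ± 2.10 to 224 ± 32.2 FPKM (3.29).

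The FGF receptors that lenvatinib inhibits moved apart. FGFR3 fell from 36.7 ± 2.05 to 0.525 ± 0.117 FPKM (log2 -4.63) and FGFR4 from 117 ± 11.2 to 6.05 ± 0.627 FPKM (-4.07), while FGFR1 rose from 4.04 ± 2.09 to 8.44 ± 0.248 FPKM (1.01). These were the 3 tested members of 10 target receptors in the files (camera adjusted p = 0.146). The FGFR1 call ended when any of the resistant replicates was left out (adjusted p from 0.0817 to 0.0941) and with no filter (limma adjusted p = 0.0679). Among other receptor kinases and growth factors, 8 of 14 rose, 4 fell and 2 did not pass (camera adjusted p = 0.294). FGF2 rose from 0.236 ± 0.106 to 33.9 ± 2.63 FPKM (4.82), the receptor AXL from 9.61 ± 3.43 to 205 ± 10.7 FPKM (4.34) and its ligand GAS6 from 0.0266 ± 0.0376 to 12.6 ± 1.37 FPKM (3.72). KLB, the co-receptor through which FGF19 acts on FGFR4, fell from 11.3 ± 0.870 to 0.0621 ± 0.0417 FPKM (-3.54).

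Of 9 tested ABC drug efflux transporters 2 rose, 6 fell and 1 did not pass (camera adjusted p = 0.12). ABCC2 fell by 4.64, ABCG2 by 3.22 and ABCC6 by 2.26 on the log2 scale. ABCC3 rose from 0.0574 ± 0.0601 to 9.21 ± 2.14 FPKM (3.25).

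Every tested transcript of the hepatocyte list fell, 23 of 23, with a median log2 fold change of -5.35 (camera adjusted p = 2.99e-11, and adjusted p = 0.203 with an estimated correlation). The files held 29 members of this list. SERPINA1 went from 2252 ± 157 to 13.2 ± 6.74 FPKM, FGA from 409 ± 12.9 to 1.37 ± 0.942 and FGG from 417 ± 67.1 to 2.15 ± 1.66 FPKM. The list holds the secreted proteins together with regulators that include HNF4A, FOXA1, FOXA2 and CEBPA. HNF4A, chosen here after its values were seen, fell from 29.7 ± 6.59 to 0.0655 ± 0.0315 FPKM (-4.82). It passed the filter through the sensitive libraries alone. Resistant replicate 2 held more of these transcripts than the other resistant libraries. SERPINA1 stood at 20.9 FPKM there, against 10.0 and 8.66, and FGA at 2.46 FPKM, against 0.919 and 0.744. Over 45 genes of at least 50 FPKM in every sensitive library and a mean over resistant replicates 1 and 3 of at most 2% of the sensitive mean, resistant replicate 2 kept a median of 1.018% of the sensitive level, against 0.307% and 0.364%.

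**Figure D3:**
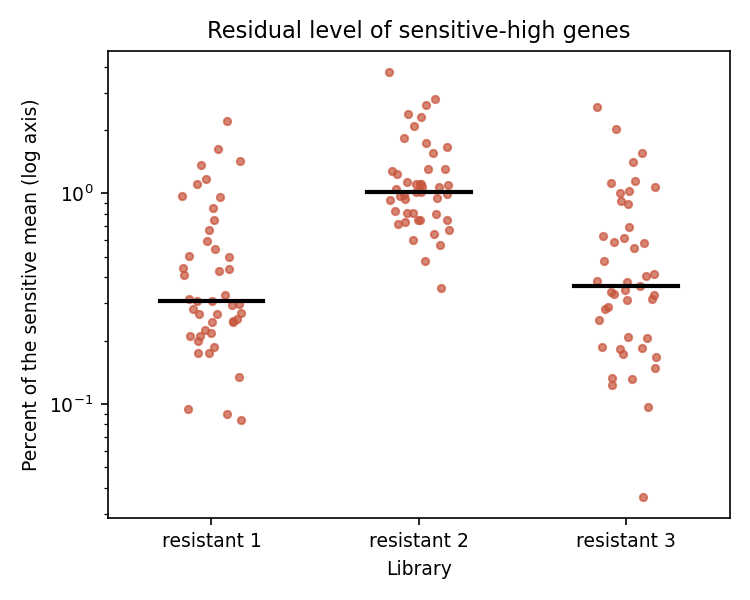
Level of those 45 genes in each resistant library as a percent of the sensitive mean, on a log axis, with 1 point per gene and a bar at the median. Resistant replicate 2 has its median at 1.018% and was the highest of the 3 resistant libraries for 44 of the 45 genes. The genes were picked by low levels in resistant replicates 1 and 3 alone, which favours replicate 2 in both values.

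All 5 tested cytochrome P450 and phase II genes fell (camera adjusted p = 0.00526, and adjusted p = 0.203 with an estimated correlation). They were the tested members of 23 in the files, and the others were below the filter. CYP1A1 fell by 4.09 and the glutathione transferase GSTP1 by 2.67, from 1788 ± 787 to 264 ± 10.4 FPKM. UGT2B4 and SULT1A1 fell by 2.01 and 1.58, but passed the filter through the sensitive libraries alone. Of 15 tested fetal liver and progenitor markers 12 fell and 3 rose (camera adjusted p = 0.00541, and adjusted p = 0.475 with an estimated correlation). The aldehyde dehydrogenase ALDH1A1 fell from 282 ± 14.5 to 1.90 ± 1.37 FPKM (-6.71) and the surface glycoprotein CD24 from 162 ± 2.11 to 1.1 ± 0.393 FPKM (-6.30). The hyaluronan receptor CD44 rose from 0.294 ± 0.053 to 101 ± 7.92 FPKM (6.30) and keratin KRT7 from 0.498 ± 0.408 to 106 ± 8.64 FPKM (6.19).

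Epithelial and mesenchymal transcripts each went both ways. E-cadherin (CDH1) fell from 15.8 ± 1.82 to 0.276 ± 0.145 FPKM (log2 -3.72), the tight junction protein CGN fell by 3.18 and the splicing regulator ESRP2 by 3.17, while the desmosomal gene PKP3 rose by 3.58. Of 15 tested epithelial genes 7 rose, 7 fell and 1 did not pass (camera adjusted p = 0.596). Of 12 mesenchymal genes 7 rose, 3 fell and 2 did not pass (camera adjusted p = 0.198). The hyaluronan receptor CD44, also on this list, rose by 6.30, whereas fibronectin (FN1) fell from 802 ± 57.6 to 10.8 ± 3.31 FPKM (-6.12) and TGFBI from 172 ± 7.30 to 6.05 ± 1.62 FPKM (-4.64).

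YAP/TAZ target genes moved upward, 14 of 18 with none lower and 4 not past the test (camera adjusted p = 0.000211, and adjusted p = 0.203 with an estimated correlation). FJX1 rose by 5.48, the ectonucleotidase NT5E by 3.92 and the kinase NUAK2 by 3.34, and AXL is also on this list. Wnt/beta-catenin targets moved downward, with 8 of 9 lower and 1 higher (camera adjusted p = 0.00541, and adjusted p = 0.244 with an estimated correlation). The files held 16 members, and TBX3, RNF43 and LGR5 passed the filter through the sensitive libraries alone. TBX3 fell from 20.5 ± 1.47 to 0.127 ± 0.0319 FPKM (-4.25), the ubiquitin ligases RNF43 and ZNRF3 by 3.02 and 1.98, and the stem cell receptor LGR5 by 2.15. TGF-beta and BMP response genes split, with 8 of 19 up, 10 down and 1 not past the test (camera adjusted p = 0.499). The helix-loop-helix regulators ID2 and ID4 fell by 5.46 and 5.28 and the decoy receptor BAMBI by 5.06.

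Of 20 tested inflammatory genes 15 rose, 3 fell and 2 did not pass (camera adjusted p = 0.00187, and adjusted p = 0.203 with an estimated correlation). IL6 went from 0.214 ± 0.0625 to 314 ± 5.12 FPKM, the cytokine LIF from 0.158 ± 0.0752 to 182 ± 10.2 FPKM (log2 7.31), LCN2 rose by 4.95 and the chemokine CXCL2 by 4.13. Of 19 type I interferon response genes 15 fell, 2 rose and 2 did not pass (camera adjusted p = 0.00258, and adjusted p = 0.485 with an estimated correlation). IFITM3, a restriction factor against enveloped viruses, fell from 649 ± 125 to 4.85 ± 4.51 FPKM (-7.04, and -7.63 without resistant replicate 2, which held 10.1 FPKM), and IFI6, ISG15 and IFIT1 fell by 3.60, 3.31 and 3.18. Antigen presentation genes showed no common direction, with 3 of 14 up, 4 down and 7 not past the test (camera adjusted p = 0.839). The immunoproteasome subunit PSMB8 rose by 4.45, and CD276 and B2M fell by 1.65 and 1.36. Without sensitive replicate 3, 7 members of that list were higher, after rescaling without mitochondrial mRNAs 5 were, and without sensitive replicate 1 the camera direction turned.

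All 5 tested metallothioneins, small metal-binding proteins, rose (camera adjusted p = 0.00127, and adjusted p = 0.203 with an estimated correlation). The files held 6, and MT1E and MT1F passed the filter through the resistant libraries alone. MT2A went from 5.05 ± 0.339 to 1847 ± 79.5 FPKM, MT1E from 0.339 ± 0.175 to 662 ± 58.9 FPKM, and MT1X rose by 3.79. MT1F was listed at 0 in each sensitive library and at 30.8, 21.9 and 21.8 FPKM in the resistant ones. Metallothionein genes are near-identical copies, so how reads were divided among them is uncertain.

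Among p53 targets, 10 of 17 rose, none fell and 7 did not pass (camera adjusted p = 0.0141, and adjusted p = 0.234 with an estimated correlation). The kinase PLK2 rose from 0.141 ± 0.106 to 160 ± 21.6 FPKM (log2 7.14), GADD45A by 5.21, the cell cycle inhibitor CDKN1A from 6.97 ± 1.94 to 140 ± 13.5 FPKM (4.16) and PLK3 by 2.69. GADD45A was at 9.31, 8.93 and 37.2 FPKM in sensitive replicates 1, 2 and 3, and its log2 fold change was 5.85 without sensitive replicate 3. Under quantile normalization, under scaling to the geometric mean sample, and without resistant replicate 3, 1 member of the list was called lower.

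DNA replication genes leaned downward in resistant cells, with 13 of 25 S phase genes lower, none higher and 12 not past the test (camera adjusted p = 0.0141, and adjusted p = 0.679 with an estimated correlation). With fry this list did not pass either (adjusted p = 0.0506). MCM3 fell from 121 ± 17.1 to 20.0 ± 2.00 FPKM (log2 -2.54), RFC4 by 1.63, MCM5 by 1.28 and MCM6 by 1.22. Without sensitive replicate 3, 21 S phase genes were lower, without resistant replicate 1 or resistant replicate 3 there were 8, and without sensitive replicate 1 there was 1 higher. G2/M genes went both ways, with 5 of 24 up, 5 down and 14 not past the test, or 2 up and 3 down adjusted over the list alone (camera adjusted p = 0.987). UBE2C rose by 2.25, while AURKA fell by 1.05, KIF20A by 0.94 and PLK1 by 0.89. The direction of the list depended on the scaling and on single libraries. It turned to the lower side under scaling to the geometric mean sample, without resistant replicate 1 or 2, and without sensitive replicate 3, where 12 members were lower and 7 higher. Other counts moved too, to 10 higher without sensitive replicate 1, 2 higher and 3 lower without sensitive replicate 2, 2 higher without resistant replicate 1, 2 higher and 3 lower without resistant replicate 2, and 3 higher and 3 lower without resistant replicate 3. After rescaling without mitochondrial mRNAs 3 were lower. Sensitive replicate 3 had lower levels of these genes than the other sensitive libraries, by a median of -0.98 for the G2/M list and -0.63 for the S phase list. PLK1 kept its call only without sensitive replicate 3 among the left-out libraries (adjusted p from 0.0869 to 0.127 in the others). It also lost the call after rescaling without mitochondrial mRNAs (limma adjusted p = 0.0869) and with no filter (0.086).

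Every tested replication-dependent histone gene rose, 11 of 11 (camera adjusted p = 6.04e-06, and adjusted p = 0.203 with an estimated correlation). The files held 16 members of this list, and H4C8 and H2BC21 passed the filter through the resistant libraries alone. H2AC6 went from 2.48 ± 0.669 to 160 ± 14.5 FPKM (log2 5.54), the linker histone H1-2 from 12 ± 3.04 to 298 ± 27.6 FPKM (4.54), and H4C8 and H2BC21 rose by 5.59 and 4.91. Most messages of this kind lack a poly(A) tail, so their level can depend on how a library selects RNA, which is not given in the sources used here.

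Cholesterol synthesis transcripts fell together, 20 of 23 with 1 higher and 2 not past the test (camera adjusted p = 0.000137, and adjusted p = 0.203 with an estimated correlation). The sterol sensor INSIG1 fell from 26.7 ± 7.23 to 2.89 ± 0.406 FPKM (log2 -2.81), and MVK and TM7SF2 each fell by 2.61. Of 19 fatty acid genes 10 fell, 3 rose and 6 did not pass (camera adjusted p = 0.0712). The desaturase SCD fell from 352 ± 69.8 to 9 ± 2 FPKM (-5.14) and PPARGC1A by 2.10, whereas the lipogenic regulator SREBF1 rose by 2.14.

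Glycolysis genes went both ways. The glucose transporter SLC2A3 fell from 452 ± 88.1 to 5.15 ± 0.787 FPKM (log2 -6.19) and PGAM1 by 2.56, while the lactate transporter SLC16A3 rose from 0.211 ± 0.0676 to 56.1 ± 2.89 FPKM (5.56) and the enolase ENO2 by 5.35. Of 18 members 7 rose, 9 fell and 2 did not pass, with a median of -0.41, a mean of 0.04 and the camera test on the lower side (adjusted p = 0.624). Of 18 hypoxia genes 10 rose, 5 fell and 3 did not pass (camera adjusted p = 0.499). LOXL2 rose by 6.05 and STC2 by 2.86, and ANGPTL4 fell by 3.25. CA9 was at 15.2, 13.6 and 13.7 FPKM in the sensitive libraries and listed at 0 in each resistant one. NRF2 and glutathione genes split as well, 6 of 19 up, 10 down and 3 not past the test (camera adjusted p = 0.266). NQO1 rose from 8.40 ± 1.48 to 199 ± 11.5 FPKM (4.42), while AKR1C3, AKR1C1 and AKR1C2, reductases with near-identical sequences that can share reads, fell by 4.48, 3.38 and 3.30.

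Unfolded protein response and ATF4 genes had no common direction, with 8 of 22 up, 9 down and 5 not past the test. The list's median was -0.25 and its mean 0.22, with camera on the lower side (adjusted p = 0.839), which turned to the higher side without sensitive replicate 3. ATF3 rose by 2.93, TRIB3 by 2.91 and DDIT3 by 2.04, and the chaperone cofactor SDF2L1 fell by 2.86. TRIB3 was at 9.80, 10.1 and 56.1 FPKM in sensitive replicates 1, 2 and 3, and its log2 fold change was 3.70 without sensitive replicate 3. DDIT3 was at 33.6, 37.1 and 167 FPKM in the same libraries, its log2 fold change was 2.78 without sensitive replicate 3, and its call ended without sensitive replicate 2, resistant replicate 1 or resistant replicate 2 (adjusted p from 0.0551 to 0.06). Golgi genes other than GOLM1 did not share its rise as a group, since 4 of 24 rose with GOLM1 counted, 6 fell and 14 did not pass (camera adjusted p = 0.624). COPE, GOLM2 and TMED10 fell by 1.71, 1.56 and 1.53, and without sensitive replicate 3 there were 10 lower. Lysosome and autophagy genes split into 8 of 24 higher, 8 lower and 8 not past the test (camera adjusted p = 0.987). Their direction turned under scaling to the geometric mean sample, and without sensitive replicate 1, sensitive replicate 2, resistant replicate 1 or resistant replicate 3. Without sensitive replicate 3 there were 13 higher, and without resistant replicate 2 there were 5 lower. Sensitive replicate 3 lay above the other sensitive libraries by a median log2 of 0.59 for this list and 0.49 for the unfolded protein response list. For the Golgi list that median was -0.39. MAP1LC3B, the autophagosome protein LC3B, rose from 50 ± 12.2 to 555 ± 50.2 FPKM (3.47), and GABARAPL1 rose by 1.40. The GABARAPL1 call held without sensitive replicate 3 only among the left-out libraries (adjusted p from 0.0605 to 0.0751 in the others). With no filter it ended too (limma adjusted p = 0.055). GLA and CTSL fell by 2.04 and 1.62.

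Among markers of other cell types, only the cholangiocyte list had enough tested members for camera. Of its 5 tested members KRT7 and SOX9 rose, by 6.19 and 1.60, ANXA4 and SLC4A2 fell, by 1.71 and 0.89, and 1 did not pass. The median of that list was -0.28 and its mean 0.98, with camera on the lower side (adjusted p = 0.879). The endothelial markers ESAM and ENG, the 2 tested of 9 in the files, rose by 6.33 and 2.32. The leukocyte markers LYZ and CD68, the 2 tested of 11, fell by 7.03 and 1.91. ACTA2, the 1 tested of 11 fibroblast and stellate cell markers, was listed at 0 in each sensitive library and at 2.77, 3.22 and 2.30 FPKM in the resistant ones, and PDGFRB was below the filter, at 1.22, 1.09 and 0.526 FPKM in the sensitive libraries and at most 0.0354 FPKM in the resistant ones. No erythroid marker reached the filter, with HBA1 at 0.447 FPKM or less and AHSP at 0.0971 FPKM or less in any library.

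Mitochondrially encoded mRNAs took 16.33% to 17.38% of summed FPKM in the sensitive and 7.18% to 7.84% in the resistant libraries. Of 13 members 12 fell, none rose and 1 did not pass, while 1 rose adjusted over the list alone (camera adjusted p = 0.000211, and adjusted p = 0.389 with an estimated correlation). COX2 fell by 2.00, ND5 by 1.83, ATP6 by 1.69 and COX3 by 1.62. Under quantile normalization, and without sensitive replicate 3, 1 member was called higher. Ribosomal protein genes were lower for 19 of 41, higher for 5 and not past the test for 17 (camera adjusted p = 0.0244, and adjusted p = 0.801 with an estimated correlation). RPL4 fell by 1.98, RPS14 by 1.58, and RPLP1 and RPLP2 by 1.33 and 1.29. That call was lost under quantile normalization (adjusted p = 0.32), with 11 higher, and without sensitive replicate 3 (adjusted p = 0.206), with 11 higher. Without any of sensitive replicate 2 and resistant replicates 1, 2 and 3, in turn, 2 were higher. Sensitive replicate 3 had ribosomal protein transcripts above the other sensitive libraries by a median of 0.42. Of 14 housekeeping genes 9 fell, 3 rose and 2 did not pass (camera adjusted p = 0.142), with PGK1 and B2M at log2 fold changes of -2.34 and -1.36, and YWHAZ at 1.93.

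**Figure D4:**
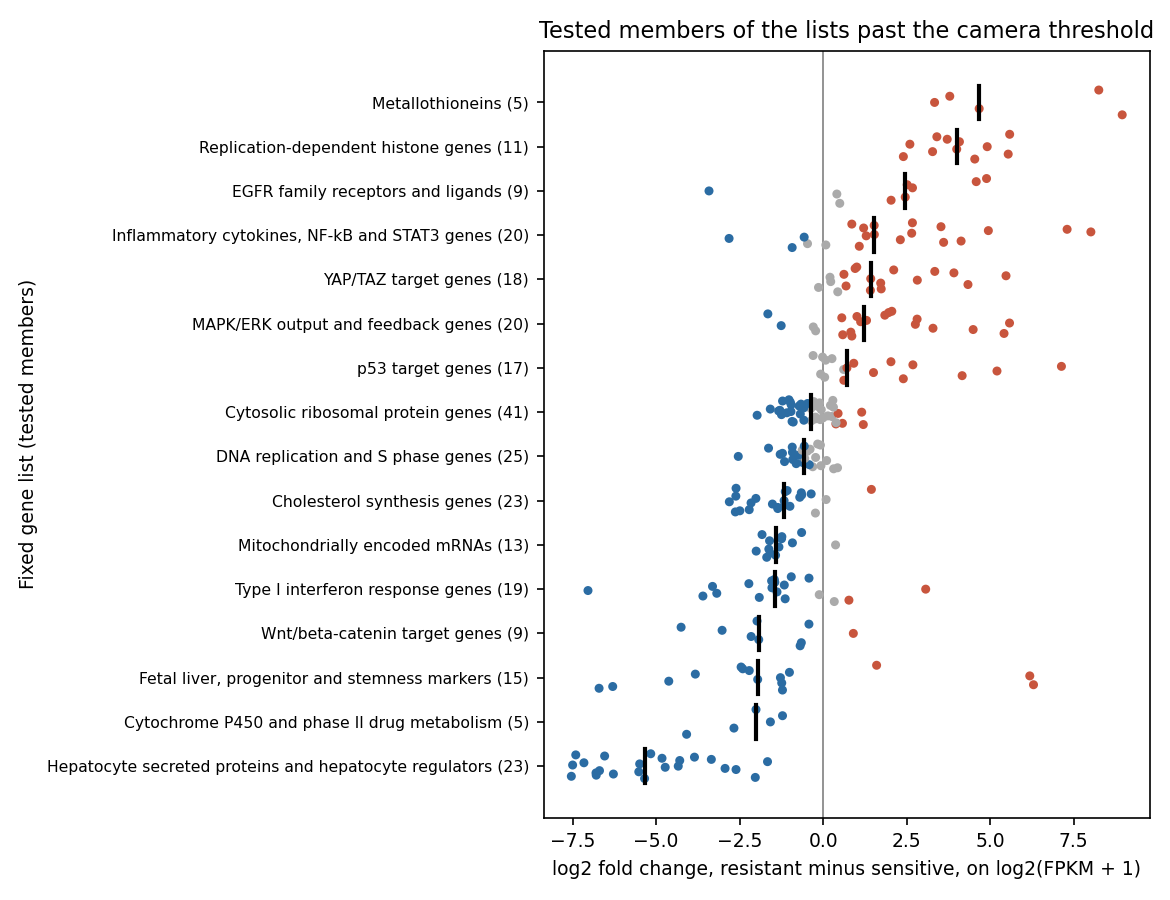
Log2 fold change of each tested member of the 16 gene lists past the camera threshold, resistant minus sensitive, on log2(FPKM + 1), with a black bar at each list's median and the number of tested members in brackets. Red and blue points passed the test as higher and lower, grey points did not, and every point of the hepatocyte list lies on the lower side.

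Across lists, 16 of the 35 with enough tested members passed the camera test, 7 on the higher and 9 on the lower side. None of the 16 calls held with an estimated correlation, where camera has only 4 degrees of freedom. The smallest unadjusted camera p there was 0.0084, for the cholesterol list, and it became 0.203 after adjustment. The estimate was below the preset 0.01 for the EGFR family (-0.07), MAPK/ERK (-0.006) and cholesterol (-0.027) lists. A higher correlation thus did not end those calls. Loss of a call under this alternative therefore does not by itself show that the members of a list vary together. For the other called lists the estimate was above 0.01, up to 0.526 for S phase genes. For 34 of 38 lists with a tested member, the counts of higher and lower members were identical adjusted over the list alone, and the other 4 are given with their lists above.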

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

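One alternative, rescaling without mitochondrial mRNAs, was chosen after the data were seen, and the others before. The counts of changed (7920), higher, lower and 2-fold changed genes stayed within 1.5 times under every scaling, limma variant, pseudocount and left-out library (6675 to 9442 changed genes over left-out libraries), and without a filter (10039). Exceptions came from testing fewer genes or a stricter hypothesis. A mean of at least 5 FPKM gave 4973 changed genes (2465 higher, 2508 lower, 2779 by at least 2-fold), and a test against a 1.5-fold change gave 4357 (2217 higher, 2140 lower), of which 4096 differed by at least 2-fold, within 1.5 times of the 4465 reported. Rescaling without mitochondrial mRNAs moved the median log2 fold change of all genes from 0.076 to 0.151 and left 7740 changed genes. The replicate block gave 7193 changed genes and 16 lists past the camera threshold. The same-numbered libraries of the groups did not deviate together (correlations across genes of -0.422, 0.072 and -0.228), and no sample correlated best with its own number. These values gave no sign of pairing, but 3 libraries per group are too few to show its absence. Of 16 lists past the threshold with camera, none (0) passed with an estimated correlation, where the test has fewer degrees of freedom. With fry, which asks if a list's genes move one way and compares them with no other genes, 28 passed. Directions turned, at adjusted p-values that follow, for lists whose members go both ways, and the cause was not tested. COP9 signalosome subunits turned with fry (0.0133), camera on ranks (0.982), quantile normalization (0.941), rescaling without mitochondrial mRNAs (0.959) and without sensitive replicate 2 (0.932), resistant replicate 2 (0.966) or resistant replicate 3 (0.984). The G2/M list turned with ranks (0.982), scaling to the geometric mean sample (1) and without sensitive replicate 3 (0.455), resistant replicate 1 (0.972) or resistant replicate 2 (0.966). Lysosome genes turned with that scaling (1) and without sensitive replicate 1 (0.805), sensitive replicate 2 (0.883), resistant replicate 1 (0.995) or resistant replicate 3 (0.984). Unfolded protein response genes turned without sensitive replicate 3 alone (0.576), antigen presentation genes without sensitive replicate 1 alone (0.993), and glycolysis genes (0.0181) and cholangiocyte markers (0.00327) with fry. Over all left-out libraries, whether or not the direction turned, the adjusted p-values ran from 0.871 to 0.993 for COP9 signalosome subunits, 0.455 to 0.972 for the G2/M list, 0.416 to 0.995 for lysosome genes, 0.576 to 0.858 for unfolded protein response genes and 0.446 to 0.993 for antigen presentation genes. Of the named genes' values under alternatives, 2331 kept direction and side of the threshold, 36 lost the call, 2 gained it (COPS5 under scaling to the geometric mean sample and without sensitive replicate 3) and 0 reversed. The FPKM values limit what can be said of genes near 0, where 1 read or fragment sets the smallest step.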

Other observations

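The families of gene symbols in the first 2 paragraphs and the tests of carry-over, of resistant cells mixed into sensitive replicate 3 and of a slower-cycling culture were chosen only after the results they bear on were seen. All 7 tested MAGE-A genes, antigens expressed in germ cells and tumours, were lower in resistant cells, with a median log2 fold change of -5.68 (camera adjusted p = 5.22e-05 over 8 families, and adjusted p = 0.199 with an estimated correlation). Of 11 MAGE-A genes in the files, these 7 passed the filter, each through the sensitive libraries alone. Their shared direction thus adds no independent support. MAGEA6 went from 93.1 ± 3.56 to 0.344 ± 0.372 FPKM and MAGEA12 from 68.3 ± 5.77 to 0.276 ± 0.188 FPKM, though near-identical members can share reads. Coagulation and complement factors outside the fixed lists fell in 15 of 17 cases with none higher (camera adjusted p = 1.55e-06, and adjusted p = 0.186 with an estimated correlation). The files held 34 such genes, and most of the 17 tested passed the filter through the sensitive libraries alone. Prothrombin (F2) went from 50.4 ± 3.25 to 0.196 ± 0.179 FPKM and complement C3 from 242 ± 29.6 to 12.5 ± 1.26 FPKM. Nuclear-encoded respiratory chain and ATP synthase subunits fell in 57 of 75 cases, with 3 higher (6 without sensitive replicate 3) and 15 not past the test (camera adjusted p = 2.8e-08, and adjusted p = 0.252 with an estimated correlation), beside the lower mitochondrially encoded mRNAs. COX5A fell from 211 ± 51.3 to 31.9 ± 1.87 FPKM and NDUFB7 from 77.2 ± 18.3 to 9.28 ± 1.33 FPKM.

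Families of cell adhesion and calcium binding did not pass camera as sets but held large single changes. Of 7 laminin chains 5 rose and 1 fell (adjusted p = 0.061), and of 10 integrin subunits 6 rose and 1 fell (adjusted p = 0.0594). The integrin counts were 7 higher and 2 lower under scaling to the geometric mean sample. Without sensitive replicate 3 they were 8 and 1. LAMB3 rose from 0.423 ± 0.279 to 123 ± 17.6 FPKM and ITGA3, a laminin-binding integrin subunit, from 2.80 ± 0.511 to 522 ± 14.5 FPKM. Of 9 annexins 6 rose and 2 fell (adjusted p = 0.0985), with ANXA1 up from 1.63 ± 0.529 to 194 ± 21.6 FPKM. Of 12 S100 genes 7 rose and 3 fell (adjusted p = 0.166), with S100P down from 64.3 ± 35.1 to 0.97 ± 0.706 FPKM. Among 25 HOX genes 9 rose and 12 fell (adjusted p = 0.52), with HOXB2 up from 0.0626 ± 0.058 to 24.5 ± 1.73 FPKM and HOXA13 down from 5.15 ± 1.39 to 0.0152 ± 0.0101 FPKM. In the main fit, the counts per direction of these families were identical adjusted over the list alone.

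Hepatocyte transcripts were lower in all resistant libraries, and 40 genes went the other way, at 0.05 FPKM or less in every sensitive and 10 FPKM or more in every resistant library, against 5 in the reverse sense (AGTR1, CA9, HULC, PIEZO2 and SLC51B), though the higher residual in the resistant libraries (next pattern) makes that limit harder to meet there. The tables argue against the scaling of whole libraries in the authors' normalization, since the median of the hepatocyte list was -5.10 or lower under each of 4 scalings. The deposited scaling is 1 of the 4. Each applies 1 factor per library, so steps that act gene by gene were not tested. Another germline in the resistant libraries, that is a line other than PLC/PRF/5, stays open, with GSTM1 off and APOBEC3B on in both groups, ERAP2 low in both (1.08, 0.813 and 0.526 FPKM in the sensitive and 0.195, 0.203 and 0.366 FPKM in the resistant libraries) and GSTT1 and UGT2B17 absent from the files. Of the 6 genes on that list of common germline null alleles 1, GSTT2B, was off in the sensitive libraries (0.0225, 0 and 0 FPKM) and on in the resistant ones (3.08, 2.29 and 3.51 FPKM), which is consistent with it but could also come from silencing in 1 state or from reads of the near-identical GSTT2. Loss of the hepatocyte program during selection under lenvatinib, which the design names, was not tested and stays open as well, and genotypes from the reads could tell the 2 apart.

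Residual sensitive-high transcripts in the resistant libraries were the second pattern. Sensitive-cell RNA or reads carried over into resistant replicate 2 would leave nearly the same percent of every such gene, and 0.0% of 45 genes lay under 10% of the median of 1.018% (quartiles 0.799% and 1.303%), but the same share was as small, 0.0% and 2.2%, against the medians of 0.307% and 0.364% in resistant replicates 1 and 3. The test thus does not single out resistant replicate 2, and carry-over cannot be told apart from index hopping between libraries, a small share of sensitive-like cells in that culture or low expression in the resistant cells. CA9 and HULC, listed at 0 in all 3 resistant libraries, and AGTR1, PIEZO2 and SLC51B, at 0.187%, 0.15% and 0.261% of the sensitive mean in resistant replicate 2, lay below a uniform share of that size, but these 5 genes were picked for being off in resistant cells and a listed 0 can be a failed estimate, so they exclude nothing. In the reverse direction, 52 resistant-high genes stood at medians of 0.146%, 0.152% and 0.208% of the resistant mean in sensitive replicates 1, 2 and 3.

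Sensitive replicate 3 stood apart, with 1079 tested genes at least 2-fold from the mean of sensitive replicates 1 and 2 (286 higher and 793 lower), against 4 genes between those 2. Resistant cells mixed into it in a share that could make 2-fold differences are argued against, since 30 genes at 0.5 FPKM or less in sensitive replicates 1 and 2 and at 50 FPKM or more in every resistant library stood there at a median of 0.109% of the resistant mean (quartiles 0.047% and 0.346%). RNA degradation or a length bias cannot be told apart from other causes, because Spearman's rho of the difference with transcript length, across 11123 genes, was -0.11, at the edge of the bound set for no trend, and the same measure gave -0.1 for resistant replicate 1 against the other resistant libraries. A slower-cycling culture may account for part of it, as the G2/M list lay at a median of -0.98, with 16 of 24 genes at least 1.5-fold lower, while lysosome and NRF2 genes lay higher by 0.59 and 0.50. Confluence and time at harvest were not tested.

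EGFR was higher in resistant cells, and a gain of the chromosome segment around it was tested as a hypothesis through the 10 nearest tested genes. Their median log2 fold change was -0.52, with none called higher and 6 lower, which argues against a gain of a segment that includes them and leaves a gain of EGFR alone open.

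The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split called 7920 genes, 1 of 10 splits reached that number, and the highest of the others called 0 genes. Each of the others mixes sensitive and resistant libraries, so a large group difference enters its residual spread. Their 0 calls thus add no support.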
